A study of Mus musculus with 28 samples.

How the data were processed

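Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, on nuclei of mouse liver. Per the labels, nuclei were released with a Dounce homogenizer, cleaned on an iodixanol gradient and tagged by the Omni-ATAC protocol. The 4 groups of the parental strains were 129S1/SvImJ on chow with 5 libraries, C57BL/6J on chow with 6, 129S1/SvImJ on a high-fat diet (HFD) with 6 and C57BL/6J on HFD with 7. Livers of 4 F1 mice of these strains were also measured. The labels give no diet for the F1 mice, and the sex of the mice is not given in the sources used here.

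The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.4b, SAMtools 1.9, Picard 2.8.13, bedtools 2.27.1, deepTools 3.4.2 and the genome build mm10. The role and order of these tools, the peak caller, the read counter and the handling of duplicate reads are not given in the sources used here. The table of the whole series holds raw counts per consensus peak, per the file headers, for 135044 peaks in 24 libraries. The 24 deposited tables of single samples hold the same counts, and each was identical to its column of the whole-series table. The deposited peak lists of single libraries hold only positions, a unit recorded as other, so their use was limited to the number and place of the peaks. The deposited F1 table holds raw counts per allele for 24271 peaks, where the reference allele is that of C57BL/6J and the alternate allele that of 129S1/SvImJ. The same deposited table lists counts at each SNP, SNP positions and the number of SNPs, units recorded as other. Each allele count equalled the sum of the counts at the SNPs of the peak, so a read over several SNPs may have been counted at each of them. The median number of SNPs per peak was 1, and 43.3% of the F1 peaks had 2 or more, up to 16. The median peak was 150 bp wide by its coordinates, and 88.3% of the peaks had this width. Coordinates are printed as in the authors' peak names, on mm10. Whether they count from 0 or from 1 could not be settled.

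Total counts per library were between 6672946 and 18055920 over the 4 groups. F1 mice had between 694839 and 754756 allele counts each, with a median of 13 to 15 counts per peak and mouse. Counts of a few per library set the precision of the weakest peaks. Intervals and limits given beside single shares cover counting error only, since reads amplified by PCR are not independent molecules. A count of 0 was taken to allow up to 3 counts. The 61 pairs of libraries within groups were checked for duplicated columns, and the lowest chi-square per degree of freedom was 2.22, well above that of a repeated library.

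Counts of the 4 groups were tested peak by peak in 1 model with a mean for each group, using edgeR 4.0.16 in R 4.3.3 with TMM factors, the quasi-likelihood F test and the expression filter of the package, which left 135031 peaks and removed 13. All such tests were two-sided, and p-values were adjusted over the peaks tested by the method of Benjamini and Hochberg, with a threshold of 0.05. The contrasts were strain on chow, strain on HFD, diet in C57BL/6J, diet in 129S1/SvImJ and the diet by strain interaction. Positive log2 values are higher in 129S1/SvImJ for strain and higher on HFD for diet. Allele counts of the F1 mice were tested with the same tool and a term for each mouse, over 9489 peaks that passed the filter. Printed levels are counts-per-million (CPM) with TMM factors, and each log2 fold change is followed by its standard error. The groups, contrasts, tests, thresholds, gene lists, rule for naming genes and most of the alternatives were fixed before the data were examined.

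Each peak was assigned to the nearest protein-coding gene if the gene's span lay within 50000 bp, which held for 89.5% of the peaks. The planned rule used transcription start sites. The gene table at hand gave spans on GRCm38.p6 without strand, so the span replaced the start site and the ends of genes replaced promoters. A total of 62.5% of the peaks lay inside a protein-coding gene and 14.3% within 1 kb of a gene end. The 20 lists held 511 genes, of which 4 had no match in the gene table. They covered bile acid, cholesterol, fatty acid, lipid droplet, glucose, insulin and xenobiotic pathways, the acute phase, zonation, the circadian clock, growth hormone targets, MHC genes and markers of hepatocytes, Kupffer cells, stellate cells, endothelial cells, cholangiocytes and lymphocytes. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation. Peaks near a list gene are not independent of each other, which the preset value does not take into account.

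Named peaks were chosen by rule. In each contrast the rule took the 6 called peaks of smallest p in each direction, 1 per gene, within the gene distance, then up to 3 called peaks of each gene list. The peaks at Tcf7l2, the factor in the title of the series, were summarized apart. Peaks printed below are a part of those the rule named, selected mostly to show lists with their most significant members, and some of the named peaks are not reported here. The imprinted genes of the F1 part were chosen after the allele counts had been seen.

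A hepatocyte index was computed for each library as the mean log2 CPM of 669 peaks of the hepatocyte list minus that of 1021 peaks of the Kupffer, stellate, endothelial and lymphocyte lists, with a prior count of 2. It was defined after the data had been examined, and so was its use as a term in the model. Group means of the index, of total counts and of the number of peaks per library were compared by two-sided exact permutation tests. Strain and allele effects were compared over peaks with identical coordinates, with exact binomial intervals at 95% and the Fisher exact test. Peaks are not independent replicates in these comparisons.

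The model was tested on simulated data, drawn peak by peak from a negative binomial distribution with the mean level and spread of the real peaks and with changes of known size added. The simulated peaks varied independently of each other, unlike those of the real libraries. Of the 4-fold changes, 86.4% were recovered for strain on chow, 92.4% for strain on HFD, 89.4% for diet in C57BL/6J, 91.7% for diet in 129S1/SvImJ, 57.6% for the interaction and 89.4% for the F1 alleles. Of the 2-fold changes, 25.4%, 38.1%, 38.8%, 29.1%, 11.9% and 50.7% were recovered in the same order. Few peaks were changed, as 67 of 135016 by 2-fold for strain on chow, where 40761 real peaks were called. The adjusted threshold is stricter when few peaks change, so these shares do not measure recovery in the real strain comparisons.

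Alternatives covered the tool (DESeq2 1.42.0, limma-trend and voom), the normalization, the count filter, thinning of all libraries to the smallest total, the groups in the model, a block for the replicate number, a random term for the number shared by mouse names, stricter thresholds, autosomes alone, the gene distance and omission of each library. Alternatives chosen after the data had been examined were the index and the first component of the deviations from group means as terms of the model, omission of the 4 libraries farthest from their group in the index, the deepest SNP of each F1 peak, and autosomes alone in the comparison of strain and allele. Intervals were handled with GenomicRanges 1.54.1 and files with the package data.table, version 1.17.8. Motif tests were not run, since no genome sequence was at hand. The annotation did not separate exons from introns, so peaks were divided into those near a gene end, inside a gene and outside genes.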

Results

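Open chromatin was mapped by ATAC-seq in livers of 129S1/SvImJ and C57BL/6J, a pair of inbred mouse strains, on chow or on HFD, and in livers of their F1 offspring. Counts over 135044 peaks were read in 24 libraries. The total count averaged 14.0 ± 3.53 M (SD, n = 5) in 129S1/SvImJ on chow and 12.9 ± 2.31 M (SD, n = 6) in C57BL/6J on chow. On HFD it averaged 14.9 ± 2.36 M (SD, n = 6) in 129S1/SvImJ and 10.3 ± 4.09 M (SD, n = 7) in C57BL/6J. Single libraries lay between 6672946 and 18055920 counts. The strains on HFD differed by 4.61 M in mean total (two-sided exact permutation p = 0.0379, adjusted p = 0.152 over 4 comparisons). The 4 F1 mice had between 694839 and 754756 allele counts each over 24271 peaks with an informative SNP.

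Liver holds hepatocytes, which make bile acids, glucose and most plasma proteins, beside Kupffer cells, stellate cells, endothelial cells and lymphocytes. The balance between peaks at hepatocyte genes and peaks at genes of the other cell types differed between libraries and was tracked as a log2 hepatocyte index. Its mean was 0.30 ± 0.67 (SD, n = 5) in 129S1/SvImJ on chow, -0.46 ± 0.44 (SD, n = 6) in C57BL/6J on chow, -0.48 ± 0.61 (SD, n = 6) in 129S1/SvImJ on HFD and -0.34 ± 0.67 (SD, n = 7) in C57BL/6J on HFD. The difference between strains was 0.76 on chow (two-sided exact permutation p = 0.0519, adjusted p = 0.152 over 4 comparisons) and -0.14 on HFD (exact permutation p = 0.719). The change with diet was -0.78 in 129S1/SvImJ (exact permutation p = 0.0758, adjusted p = 0.152) and 0.12 in C57BL/6J (exact permutation p = 0.711). None of the 4 differences passed the correction. The main axis of variation within groups, which held 48.5% of the variance of the deviations from group means, followed the deviation of the index from its group mean (r = -0.99, rho = -0.98 over 24 libraries, permutation p = 1e-05 for each, the smallest possible). The index rose with the total count over the 24 libraries (r = 0.53, permutation p = 0.00764, rho = 0.50, permutation p = 0.0121, r = 0.41 without the 2 libraries farthest from the median total). Within C57BL/6J on HFD r was 0.90 (exact permutation p = 0.00635, rho = 0.86, exact permutation p = 0.0238), and 0.58 without 2 libraries. It was 0.15 within C57BL/6J on chow (exact permutation p = 0.742, rho = 0.37), and 0.68 without 2 libraries. It was 0.47 within 129S1/SvImJ on HFD (exact permutation p = 0.393, rho = 0.14), and turned to -0.81 without 2 libraries. Adjusted over 6 relations, p was 0.0115 for the pooled relation and for C57BL/6J on HFD.

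**Figure D1:**
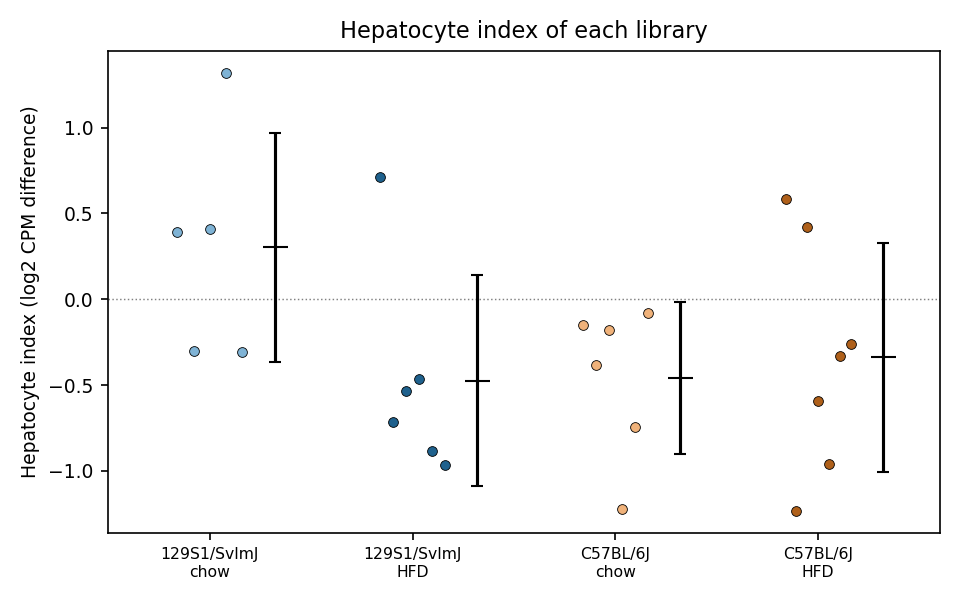
Each point is 1 library, with its hepatocyte index (log2) on the vertical axis by strain and diet, and the bars give the group mean and SD. The mean was 0.30 in 129S1/SvImJ on chow and between -0.48 and -0.34 in the other groups, and 129S1/SvImJ HFD replicate 1 lay at 0.71, apart from the others of its group.

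The comparison of the strains on chow addresses genetic determinants of chromatin availability in liver, the subject of the series. At a preset correlation between peaks the lists of Kupffer, lymphocyte and MHC genes were lower in 129S1/SvImJ and those of periportal, gluconeogenesis and lipogenesis genes higher, and each of these list calls was lost at an estimated correlation (adjusted p = 0.629). At Clec4f, a lectin receptor of Kupffer cells, the peak at chr6:83619100-83619465 had 0.480 ± 0.270 CPM (SD, n = 5) in 129S1/SvImJ and 8.72 ± 1.30 CPM (SD, n = 6) in C57BL/6J, a log2 difference of -4.19 ± 0.32 (adjusted p = 1.07e-10). At Hsd17b13, which encodes a lipid droplet enzyme, the peak at chr5:103979364-103979514 had 5.30 ± 2.46 CPM against 0.291 ± 0.123 CPM, a log2 difference of 4.16 ± 0.42 (adjusted p = 1.76e-08). Of 135031 peaks tested, 40761 (30.2%) passed the threshold, 18521 higher and 22240 lower in 129S1/SvImJ, with a median absolute log2 difference of 1.02, and 58391 had an unadjusted p under 0.05. The smallest p values in either direction included Mns1, a gene of meiosis and sperm flagella (chr9:72449501-72449651, -4.54 ± 0.19, adjusted p = 1.06e-15), Zfp40, a zinc finger gene (chr17:23193586-23193736, 2.11 ± 0.12, adjusted p = 2.21e-13), Acvrl1, a receptor of the TGF-beta family in endothelium (chr15:101148687-101148837, 3.65 ± 0.21, adjusted p = 3.73e-13), and Pik3c3, a lipid kinase of autophagy (chr18:30269197-30269347, 6.31 ± 0.32, adjusted p = 2.91e-14). At Gm13286 the 129S1/SvImJ libraries held 1 count and the C57BL/6J libraries 3114, and at Bzw1 they held 1 and 1751. Sequence missing from 129S1/SvImJ, taken up below, was not excluded for such nearly empty peaks. Of 30 named peaks examined library by library, 24 had all 11 libraries on the side of their own group, taken from the midpoint of the group means, and the others at least 10. The number of calls was 21944 without 129S1/SvImJ chow replicate 4 and 26475 without C57BL/6J chow replicate 4. All 70 peaks named by the rule kept their call when any 1 library was left out.

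Lists of immune and endothelial genes were lower in 129S1/SvImJ on chow at the preset correlation and not at an estimated one (adjusted p = 0.629). Of 219 peaks of the Kupffer cell and macrophage list, 9 were higher, 123 lower and 87 not called, and 10 were higher and 137 lower adjusted over the list alone (camera adjusted p = 1.62e-12). Examples were Itgam, an integrin of myeloid cells (-3.12 ± 0.27, adjusted p = 1.21e-09), and Cd5l, a protein secreted by macrophages (-4.76 ± 0.46, adjusted p = 6.25e-09). Of 105 lymphocyte peaks, 4 were higher, 49 lower and 52 not called, with 7 higher and 52 lower adjusted over the list alone (camera adjusted p = 8.94e-06). Its members included Pax5 (-2.80 ± 0.49, adjusted p = 1.06e-04) and Ebf1 (-2.17 ± 0.41, adjusted p = 2.83e-04), transcription factors of B cells. Of 99 MHC peaks, 4 were higher, 43 lower and 52 not called, with 4 and 47 adjusted over the list alone (camera adjusted p = 8.94e-06), among them H2-Eb1, a class II gene (-1.89 ± 0.34, adjusted p = 1.64e-04). Of 458 sinusoidal endothelial peaks, 31 were higher, 49 lower and 378 not called, with 24 and 39 adjusted over the list alone (camera adjusted p = 0.00258). Members went both ways, as at the VEGF receptor gene Flt1 (-2.20 ± 0.22, adjusted p = 1.76e-08) and at Clec4g, a lectin of sinusoidal endothelium (2.82 ± 0.34, adjusted p = 3.09e-07). The hepatocyte index was 0.76 higher in 129S1/SvImJ on chow. With it in the model the endothelial list, itself a part of the index, did not pass and had a median above 0, at 0.04 (camera adjusted p = 0.714).

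Lists of hepatocyte genes were higher in 129S1/SvImJ on chow at the preset correlation and not at an estimated one (adjusted p = 0.629). Of 357 periportal peaks, 157 were higher, 23 lower and 177 not called, with 197 higher and 25 lower adjusted over the list alone (camera adjusted p = 1.09e-12). In the gluconeogenesis list 140 were higher, 17 lower and 208 not called, with 158 and 21 adjusted over the list alone (camera adjusted p = 5.34e-09), including Ppargc1a, a coactivator of fasting metabolism (2.21 ± 0.41, adjusted p = 2.42e-04). In the lipogenesis list 154 were higher, 24 lower and 277 not called, with 177 and 25 adjusted over the list alone (camera adjusted p = 2.21e-07), including Lpin1, a phosphatidate phosphatase (3.93 ± 0.32, adjusted p = 2.13e-10). In the cholesterol synthesis list 48 were higher, 7 lower and 115 not called, with 52 and 7 adjusted over the list alone (camera adjusted p = 2.21e-07). In the list of hepatocyte transcription factors and secreted proteins 139 were higher, 24 lower and 506 not called, with 101 and 21 adjusted over the list alone (camera adjusted p = 1.79e-08). Against that direction, the peak nearest to Serpina1a, the alpha-1 antitrypsin gene, held 1 count in 129S1/SvImJ and 388 in C57BL/6J. This peak is nearly empty in 129S1/SvImJ, and sequence missing from that strain, taken up below, was not excluded for it. These 5 lists moved in the direction of the hepatocyte index, which was 0.76 higher in 129S1/SvImJ. With the index in the model 27620 peaks were called, among them 19987 (49.0%) of the calls without it. Of these 5 lists, the periportal list alone passed (camera adjusted p = 0.00873), and the Kupffer (6.10e-06), MHC (5.74e-04) and lymphocyte (0.00207) lists stayed lower, while at an estimated correlation in the same model each of these 4 lists had an adjusted p = 0.765. The hepatocyte, Kupffer and lymphocyte lists are parts of the index, so their outcomes with it in the model are partly set by its definition.

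A further 5 lists were higher on chow at the preset correlation and not at an estimated one (adjusted p = 0.629). Bile acid genes had 85 peaks higher, 17 lower and 359 not called, with 47 and 14 adjusted over the list alone (camera adjusted p = 1.06e-05), and at Fgfr4, a receptor that restrains bile acid synthesis, 129S1/SvImJ held 2 counts and C57BL/6J 349. Xenobiotic genes had 56 higher, 20 lower and 152 not called, with 74 and 20 adjusted over the list alone (camera adjusted p = 9.34e-05), including Nr1i2, which encodes the pregnane X receptor (3.25 ± 0.35, adjusted p = 4.66e-08). At Cyp2b13, a cytochrome P450 gene, 129S1/SvImJ held 0 counts, which allows up to 3, and C57BL/6J 244. For the nearly empty peaks at Fgfr4 and Cyp2b13, sequence missing from 129S1/SvImJ was not excluded. Growth hormone and sex-biased genes had 105 higher, 45 lower and 366 not called, with 101 and 41 adjusted over the list alone (camera adjusted p = 1.64e-04), including Nudt7, a peroxisomal enzyme (4.88 ± 0.37, adjusted p = 5.53e-11), and Cyp4a12a, a male-biased fatty acid hydroxylase (-5.41 ± 0.41, adjusted p = 6.85e-11). Fatty acid oxidation genes had 60 higher, 25 lower and 348 not called, with 34 and 19 adjusted over the list alone (camera adjusted p = 0.00124). Circadian clock genes had 72 higher, 36 lower and 216 not called, with 76 and 38 adjusted over the list alone (camera adjusted p = 0.00196), and Rora, a clock receptor, was lower (-3.47 ± 0.30, adjusted p = 9.52e-10). None of these 5 lists passed with the index in the model.

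The other 6 lists did not pass on chow. Lipid droplet genes had 20 peaks higher, 31 lower and 128 not called (19 and 31 adjusted over the list alone, camera adjusted p = 0.737). Insulin signalling genes had 53, 48 and 369 (29 and 38 adjusted over the list alone, camera adjusted p = 0.365), with Insr, the insulin receptor gene, lower (-2.32 ± 0.29, adjusted p = 7.90e-07). Acute phase genes had 45, 55 and 192 (55 and 58 adjusted over the list alone, camera adjusted p = 0.737). Wnt and pericentral genes had 43, 37 and 262 (37 and 36 adjusted over the list alone, camera adjusted p = 0.347). Stellate cell genes had 19, 30 and 190 (15 and 23 adjusted over the list alone, camera adjusted p = 0.347), with Reln, which encodes reelin, higher (4.73 ± 0.29, adjusted p = 8.92e-13). Cholangiocyte genes had 16, 14 and 64 (17 and 14 adjusted over the list alone, camera adjusted p = 0.0693). With the index in the model the stellate list was higher (camera adjusted p = 0.00307) and the lipid droplet list lower (camera adjusted p = 0.0319), both with an adjusted p = 0.765 at an estimated correlation. The stellate list is a part of the index, so its outcome there is partly set by the definition of the index.

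**Figure D2:**
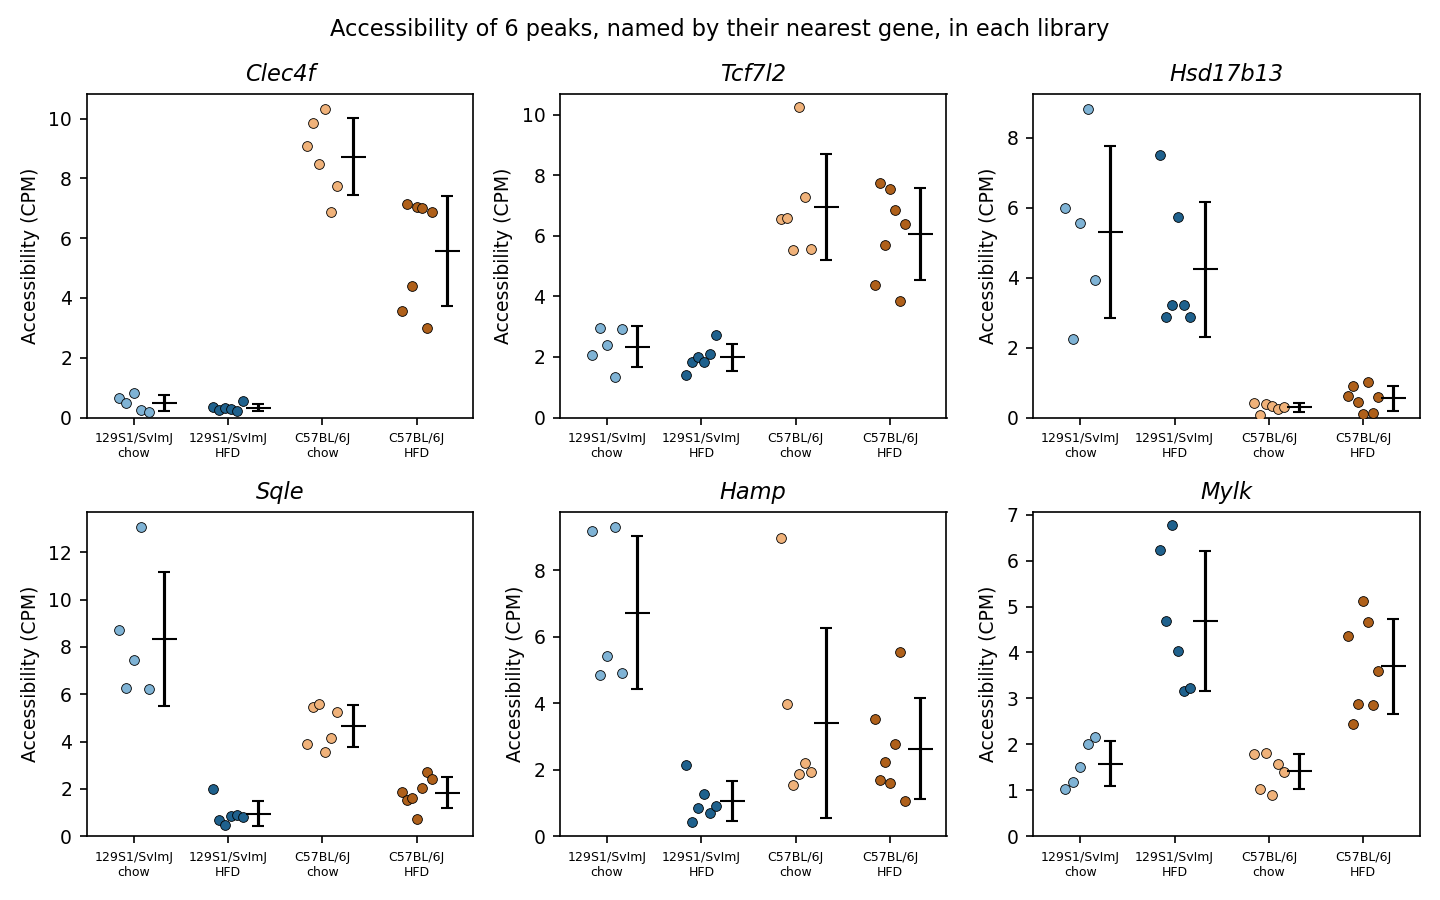
Each point is 1 library, with its level in CPM on the vertical axis by strain and diet, at 6 named peaks, and bars give the group mean and SD. Clec4f and Tcf7l2 were lower and Hsd17b13 higher in 129S1/SvImJ on both diets, while Sqle and Hamp fell and Mylk rose with HFD in 129S1/SvImJ.

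The same comparison on HFD asks for strain differences in livers of mice on the fat-rich diet. At the preset correlation the stellate and endothelial lists were higher in 129S1/SvImJ and the Kupffer, lymphocyte, MHC and lipid droplet lists lower, and each of these list calls was lost at an estimated correlation (adjusted p = 0.971). Reln was higher (4.66 ± 0.28, adjusted p = 7.67e-13), and so was Colec11, a collectin gene, at chr12:28598205-28598453 (2.65 ± 0.27, adjusted p = 1.44e-08). Clec4f was lower (-4.02 ± 0.31, adjusted p = 6.04e-11), with 29 counts in 6 libraries against 389 in 7. Cidea, which encodes a protein of lipid droplet fusion, was lower at chr18:67351891-67352041 (-2.76 ± 0.49, adjusted p = 1.11e-04). Of 135031 peaks, 20854 (15.4%) passed, 10175 higher and 10679 lower, with a median absolute log2 difference of 1.05, and 38364 had an unadjusted p under 0.05. Hivep3, a zinc finger gene, had the largest difference among the higher peaks examined (5.33 ± 0.30, adjusted p = 1.21e-13), and Mns1 (-4.35 ± 0.17, adjusted p = 1.20e-16) and Zfp40 (2.00 ± 0.11, adjusted p = 8.28e-14) kept their directions. Of 21 named peaks examined by library, 11 had all 13 libraries on the side of their own group and the others at least 10. With the hepatocyte index in the model the number of calls was 44676, and all 20854 calls without it were among them.

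Among the lists on HFD, stellate cell genes had 68 peaks higher, 15 lower and 156 not called, with 93 and 18 adjusted over the list alone (camera adjusted p = 6.93e-07), although Col4a2, a basement membrane collagen gene, was lower (-4.33 ± 0.38, adjusted p = 8.82e-10). Kupffer genes had 9 higher, 31 lower and 179 not called, with 10 and 37 adjusted over the list alone (camera adjusted p = 4.12e-04), among them Itgam (-2.71 ± 0.24, adjusted p = 8.82e-10). Lipid droplet genes had 4 higher, 32 lower and 143 not called, with 5 and 41 adjusted over the list alone (camera adjusted p = 4.12e-04), including Cd36, a fatty acid transporter (-1.30 ± 0.23, adjusted p = 9.53e-05), and, in the other direction, Hsd17b13 (2.98 ± 0.38, adjusted p = 7.02e-07). Sinusoidal endothelial genes had 40 higher, 7 lower and 411 not called, with 27 and 7 adjusted over the list alone (camera adjusted p = 0.00296), including Clec4g (2.61 ± 0.32, adjusted p = 3.23e-07). MHC genes had 2 higher, 10 lower and 87 not called, the same 2 and 10 in number adjusted over the list alone (camera adjusted p = 0.0104). Lymphocyte genes had 8 higher, 21 lower and 76 not called, with 9 and 30 adjusted over the list alone (camera adjusted p = 0.0169). The hepatocyte list had 18 higher, 31 lower and 620 not called, with 12 and 22 adjusted over the list alone (camera adjusted p = 0.0394). Each of these 7 list calls had an adjusted p = 0.971 with an estimated correlation. The hepatocyte index differed by -0.14 between the strains on HFD, less than the SD within groups, and with it in the model the endothelial and hepatocyte lists did not pass (camera adjusted p = 0.106 and 0.939). The hepatocyte, Kupffer, stellate, endothelial and lymphocyte lists make up the index, so their shifts with it in the model are partly set by its definition.

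The other 13 lists did not pass on HFD, with camera adjusted p between 0.164 and 0.966. Single metabolic genes in them still differed, in both directions. At the peaks named on chow, Lpin1 had 5.44 to 14.4 CPM in 129S1/SvImJ on HFD against 0.152 to 0.603 CPM in C57BL/6J on HFD. Nr1i2 had 7.82 to 23.4 CPM against 1.06 to 4.47 CPM. Lower in 129S1/SvImJ were Cdh1, which encodes E-cadherin of periportal hepatocytes (-3.82 ± 0.32, adjusted p = 3.81e-10), the insulin signalling genes Grb14 (-2.88 ± 0.30, adjusted p = 1.96e-08) and Akt2 (-2.30 ± 0.26, adjusted p = 8.04e-08), and Me1, the cytosolic malic enzyme (-2.61 ± 0.31, adjusted p = 1.87e-07). So were Ppara, the fatty acid receptor (-1.41 ± 0.21, adjusted p = 8.76e-06), and a peak of Sqle, the squalene epoxidase gene (-1.56 ± 0.40, adjusted p = 0.00721). In the xenobiotic, circadian, growth hormone and cholangiocyte lists the median log2 difference was above 0, at 0.07, 0.01, 0.07 and 0.02, while the mean and the camera direction were below 0.

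The strain differences of both diets were compared to see which recurred. Called on chow and on HFD were 12179 peaks, 4266 higher and 7902 lower on both diets and 11 in opposite directions, where independent lists would share 1396 and 1759. Over all peaks the log2 differences had r = 0.76 and rho = 0.53, across peaks that are not independent replicates. A peak called on 1 diet and not on the other is not shown to differ between diets, and the interaction test below called 0 peaks.

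**Figure D3:**
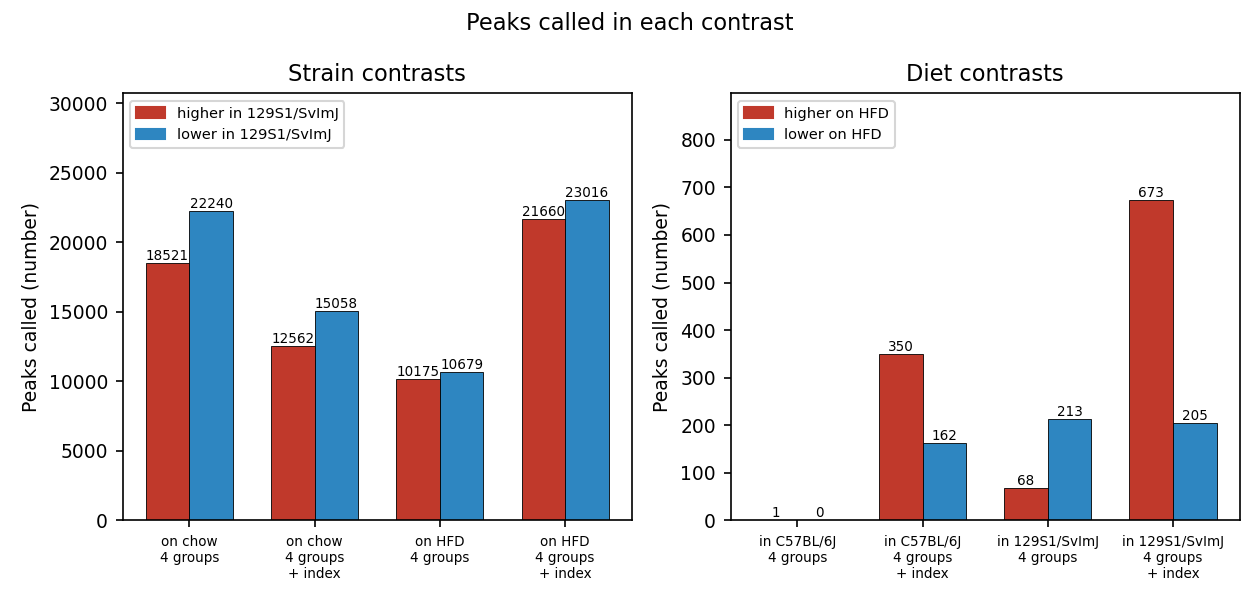
Bars give the number of peaks called higher or lower (edgeR, adjusted p under 0.05) in each comparison, on a vertical axis that starts at 0, without and with the hepatocyte index in the model. Strain on chow called 40761 peaks without the index and 27620 with it, strain on HFD 20854 and 44676, and diet in 129S1/SvImJ 281 and 878.

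The effect of HFD within 129S1/SvImJ addresses the diet arm of the design. Of the peaks near genes of cholesterol synthesis 7 of 170 fell, of lipogenesis 9 of 455 and of gluconeogenesis and glucose handling 23 of 365, and the calls of these 3 lists were lost at an estimated correlation (adjusted p = 0.376). Sqle, which encodes squalene epoxidase, fell at chr15:59317129-59317279 from 8.34 ± 2.84 CPM (SD, n = 5) to 0.947 ± 0.528 CPM (SD, n = 6), a log2 change of -3.10 ± 0.30 (adjusted p = 4.93e-06). Hamp, the hepcidin gene of iron balance, fell at chr7:30940236-30940386 from 6.72 ± 2.31 to 1.05 ± 0.605 CPM (-2.65 ± 0.43, adjusted p = 0.0153), and Mylk, a myosin light chain kinase gene, rose at chr16:35006272-35006518 from 1.58 ± 0.494 to 4.68 ± 1.52 CPM (1.54 ± 0.27, adjusted p = 0.0200). Rapgef1, a guanine exchange factor gene (-2.26 ± 0.26, adjusted p = 8.41e-05), and Tekt5, a tektin gene (-2.71 ± 0.36, adjusted p = 7.94e-04), also fell, and Deup1, a centriole gene (1.83 ± 0.25, adjusted p = 0.00108), Srgap3 (1.75 ± 0.30, adjusted p = 0.0174) and Mettl21c (2.61 ± 0.45, adjusted p = 0.0181) rose. In total 281 peaks passed, 68 higher and 213 lower, with a median absolute log2 change of 1.55, and 29157 had an unadjusted p under 0.05. Of 22 named peaks examined by library, 8 had all 11 libraries on the side of their own group and the others at least 9. DESeq2 called 2156 peaks and limma-trend 157, and a model of these 2 groups alone called 8.

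Single libraries set the number of diet calls in 129S1/SvImJ. It was 25946 without HFD replicate 1, whose hepatocyte index stood apart from its group, and 22, 44, 31, 10 and 11 without HFD replicates 2, 3, 4, 5 and 6. It was 7, 495, 19, 6 and 928 without chow replicates 1, 2, 3, 4 and 5. Of the 30 peaks named by the rule, those at Sqle, Rapgef1, Tekt5 and Deup1 kept their call whichever library was left out, and the others kept it in 2 to 8 of the 11 omissions. With the hepatocyte index in the model 878 peaks passed, 673 higher and 205 lower, including 197 (70.1%) of the 281.

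By list, gluconeogenesis and glucose handling had 0 peaks higher, 23 lower and 342 not called on HFD in 129S1/SvImJ, with 4 higher and 132 lower adjusted over the list alone (camera adjusted p = 5.34e-22). Examples were G6pc, the glucose-6-phosphatase gene (-2.13 ± 0.39, adjusted p = 0.0221) and the glycogen synthase gene Gys2 (-1.66 ± 0.33, adjusted p = 0.0301). Cholesterol synthesis had 0 higher, 7 lower and 163 not called, with 1 and 34 adjusted over the list alone (camera adjusted p = 3.80e-17). Lipogenesis had 0, 9 and 446, with 6 higher and 63 lower adjusted over the list alone (camera adjusted p = 1.47e-13), including Fasn, the fatty acid synthase gene (-2.21 ± 0.41, adjusted p = 0.0233), Fads1, a desaturase (-1.81 ± 0.33, adjusted p = 0.0204), and Acly, the ATP citrate lyase gene (-2.13 ± 0.43, adjusted p = 0.0352). Periportal genes had 0, 3 and 354, with 1 and 53 adjusted over the list alone (camera adjusted p = 4.94e-21), including Etnppl, a phospholyase gene (-2.71 ± 0.54, adjusted p = 0.0308). The hepatocyte list had 0, 2 and 667, with 0 and 5 adjusted over the list alone (camera adjusted p = 7.46e-19). Each of these 5 lists had an adjusted p = 0.376 with an estimated correlation. They moved in the direction of the hepatocyte index, which changed by -0.78 on HFD. With the index in the model the cholesterol (camera adjusted p = 7.09e-06), gluconeogenesis (9.40e-06) and periportal (0.0222) lists stayed lower, with adjusted p of 0.188, 0.188 and 0.444 at an estimated correlation. The lipogenesis list then had 6 peaks higher and 6 lower and did not pass (camera adjusted p = 0.152).

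In 13 further lists the diet effect in 129S1/SvImJ passed with few or no called peaks. Growth hormone genes had 0 peaks higher and 4 lower, with 0 and 7 adjusted over the list alone (camera adjusted p = 1.81e-09), including Cux2, a transcription factor gene (-2.15 ± 0.39, adjusted p = 0.0221). Bile acid genes had 0 higher and 1 lower, at Slc10a1, the bile acid uptake transporter (-1.57 ± 0.29, adjusted p = 0.0241), and the same number adjusted over the list alone (camera adjusted p = 1.51e-08). Insulin signalling had 1 higher, at the kinase gene Sik1 (1.11 ± 0.22, adjusted p = 0.0305), and 1 lower, at Pik3r1, a regulatory subunit of PI3-kinase (-1.23 ± 0.24, adjusted p = 0.0274), with 3 and 4 adjusted over the list alone (camera adjusted p = 0.0379). Fatty acid oxidation (5.38e-05), xenobiotic (5.10e-04), circadian (6.47e-04), cholangiocyte (0.00153) and Wnt (0.00479) lists were lower by camera adjusted p. Kupffer (1.43e-10), endothelial (3.01e-08), stellate (2.18e-07), MHC (0.00102) and lymphocyte (0.0102) lists were higher by camera adjusted p, with 0 called peaks in each by edgeR. With an estimated correlation all 13 had an adjusted p between 0.376 and 0.458. With the index in the model the bile acid, fatty acid oxidation, xenobiotic and cholangiocyte lists passed as higher at the preset correlation and not at an estimated one (adjusted p between 0.188 and 0.444). Acute phase genes had 0 higher and 5 lower, all at Hamp, with 16 higher and 7 lower adjusted over the list alone (camera adjusted p = 0.632), and lipid droplet genes had 0 and 0, with 3 and 0 adjusted over the list alone (camera adjusted p = 0.611).

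In C57BL/6J the effect of HFD passed at 1 peak. Ccdc57, a coiled-coil gene next to Fasn, rose at chr11:120878216-120878366 from 0.949 ± 0.299 CPM (SD, n = 6) to 3.21 ± 1.22 CPM (SD, n = 7), a log2 change of 1.79 ± 0.27 (adjusted p = 0.0497), in the called direction in 13 of 13 libraries. In 129S1/SvImJ its log2 change was 0.73 (adjusted p = 0.173). DESeq2 called 69 peaks and limma-trend 0, and 7972 peaks had an unadjusted p under 0.05. The call at Ccdc57 was lost in a model of the 2 groups alone (adjusted p = 0.225), and without C57BL/6J chow replicate 1, 2, 3, 4 or 6 or HFD replicate 1, 3 or 7, where 0 peaks were called. Without HFD replicate 2 and HFD replicate 4 the counts were 2 and 3. Lipid droplet genes had 5 peaks higher and 0 lower adjusted over the list alone (camera adjusted p = 1.62e-08, adjusted p = 0.225 with an estimated correlation), lipogenic genes 3 and 0 (camera adjusted p = 3.28e-05) and cholesterol genes 0 and 1 (camera adjusted p = 0.251). Periportal (1.62e-08), fatty acid oxidation (7.12e-06), xenobiotic (7.12e-06), bile acid (1.43e-05), hepatocyte (5.13e-05) and circadian (0.0391) lists were higher and stellate (4.43e-06), endothelial (2.80e-05) and lymphocyte (0.0215) lists lower by camera adjusted p, with 0 called peaks in each by edgeR. With an estimated correlation these lists and the lipogenic list had an adjusted p between 0.697 and 0.763. In the MHC list the median of 0.02 and the mean of 0.06 were above 0 and the camera direction was below, and in the Wnt list the median of -0.01 and the mean of 0.01 differed in sign, both lists not called (camera adjusted p = 0.674). The hepatocyte index changed by 0.12, and with it in the model 512 peaks passed, 350 higher and 162 lower. The lipogenic, periportal, fatty acid oxidation, xenobiotic, bile acid, hepatocyte, circadian and lymphocyte lists then did not pass (camera adjusted p between 0.102 and 0.736). The hepatocyte and lymphocyte lists are parts of the index.

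Whether the response to HFD differed between the strains was tested as an interaction. At Sqle the log2 change was -3.10 in 129S1/SvImJ and -1.35 in C57BL/6J (adjusted p = 0.244), and the interaction had an adjusted p = 0.314. At Mylk it was 1.54 in 129S1/SvImJ and 1.39 in C57BL/6J (adjusted p = 0.164), with an interaction adjusted p = 0.817. The smallest adjusted p was 0.220, at Deup1. In total edgeR called 0 peaks, with 20984 at an unadjusted p under 0.05, DESeq2 called 7 and limma-trend 0. Without 129S1/SvImJ HFD replicate 1 edgeR called 1. Adjusted over the list alone, 40 periportal, 11 lipogenic and 6 cholesterol peaks had a lower response in 129S1/SvImJ and 1 stellate peak a higher one. With the index in the model 1 periportal peak had a lower response, and the lipogenic, cholesterol and stellate lists had 0 such calls. The lipid droplet list then had 1 lower, and the acute phase and Wnt lists 1 higher each. By camera 19 of the 20 lists passed, 14 lower and 5 higher, with the periportal list lowest in p (camera adjusted p = 1.82e-22), and 0 passed with an estimated correlation, where the smallest adjusted p was 0.362. The index itself had an interaction of -0.90 (permutation p = 0.0963). The diet effects of the strains had r = -0.07 and rho = -0.15 over all peaks, 0 shared calls and, among the 281 calls of 129S1/SvImJ, 80.4% with the same sign in C57BL/6J, against 40.4% over all peaks. With the index in the model the relation turned, with r = 0.26, rho = 0.20 and 55.5% of the same sign over all peaks.

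**Figure D4:**
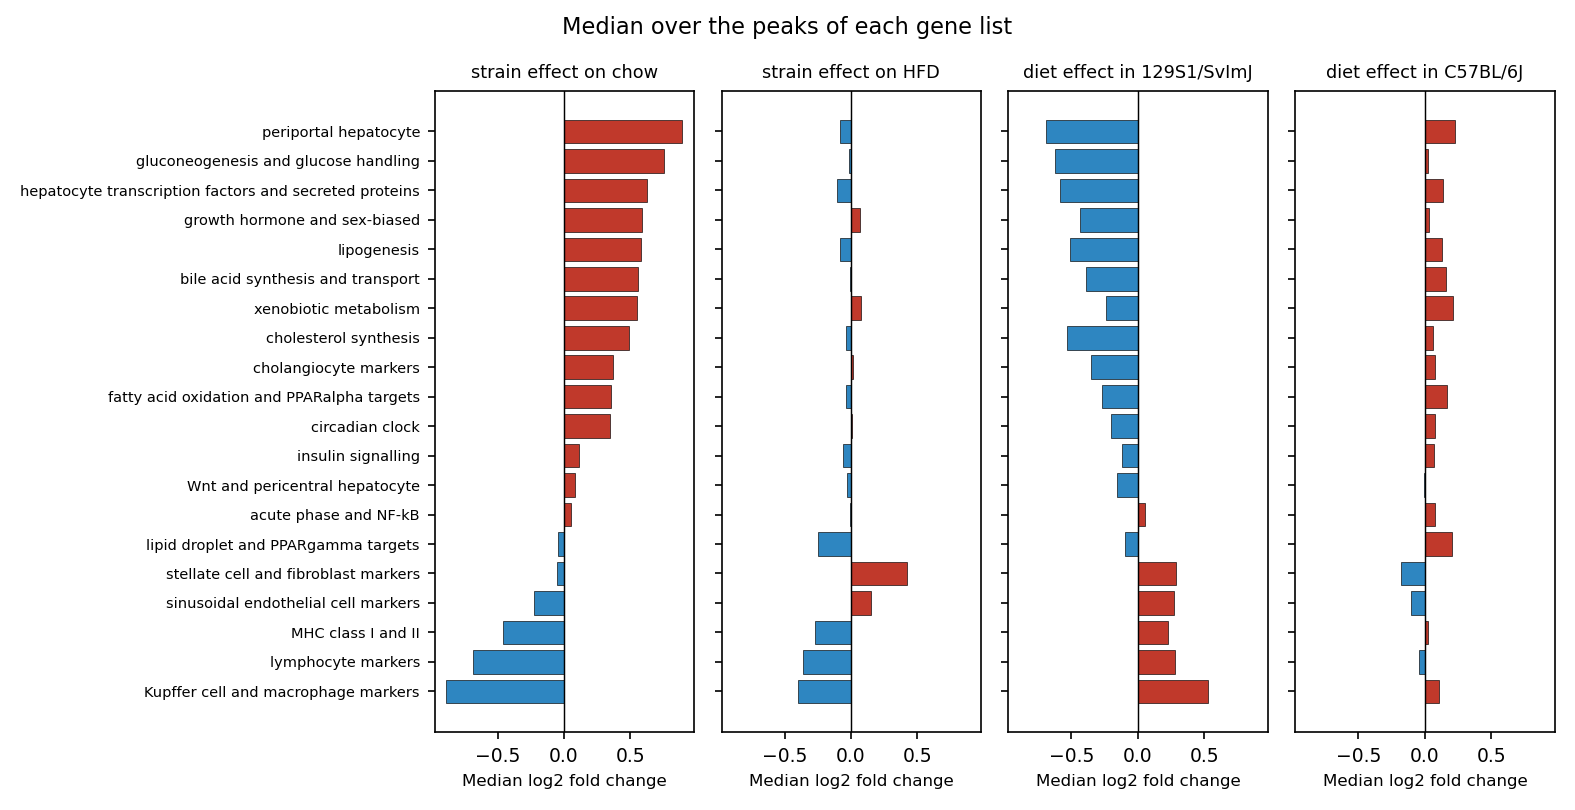
Bars give the median log2 difference (horizontal axis) over the peaks of each of 20 gene lists (vertical axis) in the comparisons of strain on chow, strain on HFD, diet in 129S1/SvImJ and diet in C57BL/6J. Kupffer genes lay at -0.89 for strain on chow and -0.40 for strain on HFD, and periportal genes at 0.89 for strain on chow and -0.70 for diet in 129S1/SvImJ.

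In F1 livers both autosomal alleles share the same nuclei and the same mix of cells. This tells differences between alleles from differences in the mix of cells. The labels do not give the direction of the cross. If it was the same in all mice, an effect of the allele and one of its parent of origin cannot be told apart. The calls below include 24 peaks on the X chromosome and some at imprinted genes. At Clec4f the 129S1/SvImJ allele held 30 counts and the C57BL/6J allele 444, 6.33% on the former and a log2 ratio of -3.82 ± 0.25 (adjusted p = 6.00e-07). Hivep3 held 400 and 9 counts, 97.8% on the 129S1/SvImJ allele (5.41 ± 0.29, adjusted p = 2.78e-07), and Zfp40 held 566 and 161, 77.9% (1.84 ± 0.15, adjusted p = 4.19e-06). Clec4g (106 and 9, 3.52 ± 0.59, adjusted p = 7.46e-04), Colec11 (136 and 28, 2.30 ± 0.38, adjusted p = 6.37e-04), Acvrl1 (114 and 19, 2.58 ± 0.37, adjusted p = 2.10e-04) and Nudt7 (183 and 4) were higher on the 129S1/SvImJ allele. So was Acadl, an acyl-CoA dehydrogenase gene (71 and 6, 3.54 ± 0.59, adjusted p = 6.79e-04). Itgam held 2 and 60 counts and Fgg, a fibrinogen gene, 3 and 126. The direction was the same in all 4 mice at these peaks. At Hsd17b13 the counts were 26 and 0, too few for the test, and the 0 allows up to 11.5%. Of 9489 peaks tested, 1990 passed, 949 higher and 1041 lower on the 129S1/SvImJ allele, with a median absolute log2 ratio of 1.69, and 2909 had an unadjusted p under 0.05. DESeq2 called 1640. Counting the deepest SNP of each peak alone gave 1012, with the filter applied anew to the lower counts. Of 49 peaks named by the rule in F1, 23 were then not tested, and 24 of the 26 tested kept their call.

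Allelic peaks near list genes were few. The hepatocyte list had 2 higher, 6 lower and 30 not called, with 2 and 6 adjusted over the list alone, including Serpina1a at chr12:103863652-103863802 (8 and 81 counts, -3.25 ± 0.45, adjusted p = 1.61e-04). Growth hormone genes had 4, 1 and 14, with 4 and 3 adjusted over the list alone, including Cish, an inhibitor of cytokine signalling (9 and 174 counts, -4.24 ± 0.52, adjusted p = 6.89e-05). Gluconeogenesis genes had 3, 2 and 26, with 3 and 2 adjusted over the list alone, and Ppp1r3b, a glycogen-targeting subunit, held 3 and 92 counts. Fatty acid oxidation genes had 2, 2 and 26, with 2 and 2 adjusted over the list alone, including Ppara at chr15:85698721-85698987 (23 and 93 counts, -1.96 ± 0.37, adjusted p = 0.00164). Kupffer genes had 1, 3 and 7, lipogenic genes 3, 0 and 21, endothelial genes 3, 1 and 21, stellate genes 2, 1 and 9 and acute phase genes 0, 2 and 13. The lipogenic count included Lpin1 at chr12:16639491-16639641 (74 and 23 counts, 1.79 ± 0.59, adjusted p = 0.0486, 3 of 4 mice), a call lost at a common library size for both alleles. It was kept in 1 of 4 omissions of a mouse and lost without F1 replicate 1 (2.07, adjusted p = 0.109), F1 replicate 3 (1.33, adjusted p = 0.143) or F1 replicate 4 (1.43, adjusted p = 0.157). Of 49 peaks named by the rule in F1, 40 kept their call whichever mouse was left out. Orm3, an acute phase gene (34 and 163 counts, -2.24 ± 0.54, adjusted p = 0.00897, 3 of 4 mice), and Epcam, an epithelial adhesion gene (57 and 183 counts, -1.65 ± 0.24, adjusted p = 2.58e-04), were lower on the 129S1/SvImJ allele. The lipid droplet list had 0 calls among 6 peaks by edgeR, and no MHC peak was tested.

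Strain and allele effects were compared at the same peaks to see how far strain differences recurred between alleles. Among the 9489 peaks, 3920 were called between strains on chow, and 84.9% of these (exact binomial 95% interval 83.7 to 86.0) had the same sign between alleles. On HFD 2900 were called and 91.8% (90.7 to 92.8) had the same sign. Over all 9489 peaks, called or not, the share was 68.4% for chow and 71.6% for HFD. With the hepatocyte index in the model the share among called peaks was 88.7% for chow and 85.5% for HFD, so the order of the diets turned. Called in both tests were 1545 peaks for chow, 688 higher, 842 lower and 15 in opposite directions, and 1506 for HFD, 728 higher, 769 lower and 9 in opposite directions. Over all 9489 peaks r was 0.76 and rho 0.60 for chow, and r was 0.80 and rho 0.68 for HFD, across peaks that are not independent replicates. Of the allelic calls, 77.6% were also called between strains on chow and 75.7% on HFD. The share with the same sign was 96.1% among 2086 peaks called on both diets and 72.1% among 1834 called on chow alone (Fisher exact p = 1.11e-103, which takes peaks as independent). A call on both diets favours larger and surer differences, and their size was not matched. The higher share is thus partly set by the selection and does not show that differences called on chow alone are of another kind.

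Peaks with an informative SNP were called between strains more often, 45.5% against 26.8% of other peaks on chow and 35.2% against 11.1% on HFD. In 1 Mb windows without such a peak 25.9% of the peaks were called on chow and 8.93% on HFD, and in windows with at least 20% of such peaks 35.3% and 22.3%. The differences, 9.44 and 13.4 percentage points, had a permutation p = 1e-04 over windows, the smallest possible. Peaks with an informative SNP made up 37.3% of the peaks in the latter windows and were counted there. Part of these differences thus restates the comparison of single peaks, and an effect of the region was not separated from it. Peaks near a gene end, within 1 kb, were called less often. They made up 9.56% of the calls and 16.4% of the other peaks for strain on chow (Fisher exact adjusted p = 6.50e-252), 9.21% and 15.3% for strain on HFD (adjusted p = 3.43e-127), 9.96% and 14.3% for diet in 129S1/SvImJ (adjusted p = 0.0439) and 12.9% and 26.4% for the F1 alleles (adjusted p = 9.71e-40). For diet in 129S1/SvImJ the difference was lost with a limit of 5 kb (odds ratio 0.989). The Fisher tests take peaks as independent, which they are not, so their p-values do not measure the spread between mice.

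Tcf7l2, a transcription factor of Wnt signalling and the subject of the series, had 53 peaks. On chow 11 were higher and 8 lower in 129S1/SvImJ, and on HFD 0 were higher and 8 lower. The smallest p on both diets lay at chr19:55788936-55789086, inside the gene, with 2.34 ± 0.672 CPM (SD, n = 5) against 6.96 ± 1.75 CPM (SD, n = 6) on chow (-1.58 ± 0.24, adjusted p = 1.83e-05, 11 of 11 libraries) and a difference of -1.60 ± 0.23 on HFD (adjusted p = 4.23e-06, 12 of 13 libraries). Diet called 0 of the 53 peaks by edgeR in either strain, with a smallest adjusted p of 0.834 in C57BL/6J and 0.104 in 129S1/SvImJ. In F1 mice 2 Tcf7l2 peaks were tested and 0 called, with a smallest adjusted p of 0.728.

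Some C57BL/6J peaks were nearly empty in 129S1/SvImJ. In 115 peaks the 11 libraries of 129S1/SvImJ held at most 3 counts together and the 13 of C57BL/6J at least 300, and the reverse was seen in 0 peaks. By fitted values, which depend on the prior count at such low levels, 168 peaks were at least 64-fold lower and 12 at least 64-fold higher in 129S1/SvImJ on chow, and 175 and 9 on HFD. Of the 115 peaks, 4 were in the F1 table. On the X chromosome of the F1 mice 24 of 24 tested peaks were lower on the 129S1/SvImJ allele, among them a peak near Piga, a gene of GPI anchor synthesis, at chrX:164419484-164419711 (30 and 384 counts, -3.64 ± 0.22, adjusted p = 3.04e-07). The share of X counts on that allele was 0.897% (exact 95% interval 0.464 to 1.56), 1.51% (0.939 to 2.30), 0.701% (0.337 to 1.28) and 1.01% (0.565 to 1.65) in the 4 mice, against 49.7% to 49.8% on autosomes. Impact, a paternally expressed imprinted gene, held 785 counts on the 129S1/SvImJ allele at chr18:12974094-12974359 and 0 on the other, which allows up to 0.382%. Ccdc162 held 1418 and 1 counts.

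The number of peaks the authors called in single libraries was between 26610 and 69317. It averaged 53926 ± 11615 (SD, n = 5) in 129S1/SvImJ on chow, 57411 ± 7529 (SD, n = 6) in C57BL/6J on chow, 62533 ± 6688 (SD, n = 6) in 129S1/SvImJ on HFD and 45907 ± 15703 (SD, n = 7) in C57BL/6J on HFD. The difference between strains on HFD had a two-sided exact permutation p = 0.0385, and an adjusted p = 0.154 over 4 comparisons, and the other 3 had adjusted p of 0.565, 0.214 and 0.214. The number of peaks rose with the total count (r = 0.85, rho = 0.81, permutation p = 1e-05 for each, the smallest possible, r = 0.79 without the 2 libraries farthest from the median total). The relation held within C57BL/6J on chow (r = 0.94, exact permutation p = 0.0125, adjusted p = 0.0250 over 8 relations) and C57BL/6J on HFD (r = 0.96, exact permutation p = 0.00159, adjusted p = 0.00635). Within 129S1/SvImJ on HFD it did not pass the correction (r = 0.84, exact permutation p = 0.0444, adjusted p = 0.0711). No correlation was computed over the 5 libraries of 129S1/SvImJ on chow, since at least 6 were required, and the deepest of them, replicate 4 with 18055920 counts, had 46696 peaks. In C57BL/6J on HFD the number of peaks rose with the hepatocyte index as well (r = 0.94, rho = 0.89, exact permutation p = 0.00437, adjusted p = 0.0116), which itself rose with the total count there.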

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

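The tests of explanations and of other groupings of the libraries in this part were chosen only after the results had been seen, while the search for single libraries far from their group was planned.

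A library lay far from the others of its group in 16 of 185 groups of 4 to 7 libraries or mice examined, where chance flags about 1 in 20 groups. The hepatocyte index of 129S1/SvImJ HFD replicate 1 was 0.71, against -0.46 in the nearest library of its group. The same library had 1.98 CPM at the Sqle peak of the diet comparison (nearest 0.877) and 1.63 CPM at the Fasn peak (nearest 0.754). C57BL/6J HFD replicate 1 had 4.59 CPM at Cidea (nearest 1.75) and 3.23 CPM at Me1 (nearest 2.19), C57BL/6J HFD replicate 2 had 10.8 CPM at Zfp40 (nearest 7.73), and C57BL/6J chow replicate 4 had 10.2 CPM at Tcf7l2 (nearest 7.27). In 129S1/SvImJ on HFD, replicate 6 had 0.548 CPM at Clec4f (nearest 0.349), replicate 5 had 0.760 CPM at Col4a2 (nearest 0.291) and replicate 3 had 1.92 CPM at Ppara (nearest 1.63). In 129S1/SvImJ on chow, replicate 4 had 0.487 CPM at Itgam (nearest 0.751). At 4 nearly empty peaks a count of 1 or 2 set 1 library of that group apart, with 0.118 CPM at Gm13286 in replicate 2, 0.0653 CPM at Bzw1 in replicate 5, 0.131 CPM at Fgfr4 in replicate 5 and 0.0739 CPM at Serpina1a in replicate 1, all others at 0. In F1 replicate 2 the 129S1/SvImJ allele held 99.7% of the counts at Ccdc162, against 100% in the other mice.

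Other groupings of the libraries were counted with limma-trend on the compared groups alone, over 100 splits with the real one included. For strain on chow 1 of 100 splits called as many peaks (real 48995, highest other 17036), the real one itself. This is the smallest share that 100 splits allow, and it argues against chance. For strain on HFD it was 2 of 100 (real 15083, highest other 25648), a share under 0.05. Since the 1 other split called more peaks than the real one, the count alone does not exclude chance for strain on HFD. For diet in 129S1/SvImJ it was also 2 of 100 (real 8, highest other 40188), a share under 0.05 that rests on 8 calls. The 1 other split that reached this count called far more peaks, which points to a structure of the samples. For diet in C57BL/6J (real 0, highest other 27154) and the interaction (real 0, highest other 43173) all 100 splits called as many. Any split reaches a real count of 0, so this cannot decide on chance. The large counts in other splits again point to such a structure. For the F1 alleles 8 assignments are too few for a share under 0.05 (real 1990, highest other 0). The number of gene lists called was matched or exceeded in 49 of 100 splits for strain on chow (real 14, highest other 19), 84 for strain on HFD (real 6, highest other 18), 69 for diet in C57BL/6J (real 9, highest other 19), 24 for diet in 129S1/SvImJ (real 18, highest other 19) and 13 for the interaction (real 18, highest other 19), so chance is not excluded for any of these counts of lists. The number of peaks called with the same sign between strains and between alleles was reached in 1 of 100 splits on chow (real 1556, highest other 6) and 1 of 100 on HFD (real 1410, highest other 17). Both shares are the smallest that 100 splits allow, and they argue against chance for both.

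More peaks differed between strains on chow, 40761, than on HFD, 20854. The size of this gap depends on single libraries, since the count on chow was 21944 without 129S1/SvImJ chow replicate 4 and 26475 without C57BL/6J chow replicate 4, and that on HFD was 23595 without 129S1/SvImJ HFD replicate 1. A difference in depth is argued against, since the count on chow remained 1.82 times that on HFD after all libraries were thinned to the smallest total. A lower share of hepatocytes that raises every other cell type alike is argued against as the whole of the strain difference on chow. There, at peaks without an informative SNP, the Kupffer list differed by -0.70 and the lymphocyte list by -0.58 (exact permutation p = 0.00216 each, adjusted p = 0.00541), the endothelial list by -0.19 and the stellate list by -0.14, and stellate minus Kupffer was 0.56 (exact permutation p = 0.00433). The Kupffer list lay below the stellate list on HFD too, with medians of -0.40 and 0.42, so this gap leaves such a share open for the excess on chow over HFD. At peaks without an informative SNP the diet change of 129S1/SvImJ minus that of C57BL/6J was 0.37 for the Kupffer list, 0.45 for stellate, 0.31 for endothelial and 0.24 for lymphocyte genes and -0.54 for the hepatocyte list. The 4 other cell types were not shown to move apart (exact permutation p = 0.627 for their range), and of the 5 shifts only that of the stellate list had a p under 0.05 (exact permutation p = 0.0421, not adjusted). A different mix of cell types between libraries stays open as a candidate explanation, since the adjustments disagreed. The count on chow was 0.618 times that on HFD with the hepatocyte index in the model, 1.63 times with the first component and 1.79 times without the 4 libraries farthest in the index. The index would also absorb a real strain difference at the hepatocyte genes it is made of, and the first component, taken from deviations within groups, cannot remove a shift between groups. A strain difference that depends on diet stays open too, and the interaction test called 0 peaks by edgeR, 7 by DESeq2 and 0 by limma-trend, with 20984 at an unadjusted p under 0.05. With the first component in the model far more were called, a count given below that is partly set by how the component was taken.

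Very large losses of accessibility in 129S1/SvImJ outnumbered very large gains. Reads of 129S1/SvImJ lost where SNPs are dense stay open. Of the peaks at least 64-fold lower 5.36% held 4 or more informative SNPs, but 13.1% were in the F1 table at all, and the SNPs of the others are not known here. Over 2468 F1 peaks with 4 or more SNPs 49.4% of the counts lay on the alternate allele, which shows no general loss and leaves the few empty peaks undecided. Reference sequence missing from 129S1/SvImJ stays a candidate for part of the losses. Peaks at least 64-fold lower held an informative SNP in 13.1% of cases and peaks 4- to 64-fold lower in 69.9%, a ratio of 0.187. Of all 135031 tested peaks 24268 held one, so the ratio reflects mostly the high share among the latter. The sequence of 129S1/SvImJ itself was not examined, and regulatory differences between the strains stay open for the remainder.

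On the X chromosome of the F1 mice nearly all counts lay on the C57BL/6J allele. Reads of the 129S1/SvImJ X left unaligned are argued against, since the median strain difference on chow at the X peaks with SNPs was 0.23, not strongly negative. F1 males with C57BL/6J mothers could account for it, since such mice carry the maternal X alone, and imprinted genes were read as a test of the cross. At genes with a maternally methylated region, 7 peaks called between alleles had at least 95% of their counts on the 129S1/SvImJ allele, among them 3 at Impact and 2 at Peg10. Counts of 785 and 0 at an Impact peak argue against 129S1/SvImJ mothers. At Cdh15 the 3 peaks, all too low for the test, went both ways, with 1 and 21, 6 and 58 and 48 and 9 counts on the 129S1/SvImJ and C57BL/6J alleles. Other peaks of these genes leaned to either allele, and 1 at H13 was called on the C57BL/6J side, with 34 and 117 counts (adjusted p = 0.00323). The labels give neither the sex nor the mothers of the F1 mice, and the sex was not tested by these genes.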

How the results depend on the processing

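The hepatocyte index and the first component of the deviations as terms of the model, omission of the 4 libraries farthest in the index, the deepest SNP of each F1 peak and autosomes alone for strain against allele were chosen after the data had been seen, and the other alternatives were planned. Among the values of single named peaks and gene lists, 4793 kept direction and call under the alternatives planned before the data were examined and 418 lost the call, with 2 newly called. Under those chosen later 572 kept both, 53 lost the call, 7 were newly called and 6 reversed.

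The strain calls on chow were 18140 at an adjusted p of 0.01, 21697 with a 2-fold minimum, 70195 with the first component and 21944 to 45833 when each library was left out. Those on HFD were 11485, 11323, 43029 and 16763 to 23595 in the same order, and 44676 with the index. Scaling by library size alone moved the split on chow to 11412 higher and 26379 lower, with a median shift of -0.07. The single diet call in C57BL/6J became 69 with DESeq2, 2 with quantile normalization, 4 with the replicate block, 1061 with the first component, 512 with the index and 0 to 3 when each library was left out. It became 0 with DESeq2 size factors, an adjusted p of 0.01, autosomes only, library size only, limma-trend, a mean count of at least 20, the 2 groups alone, thinned libraries or without the 4 libraries. The diet calls in 129S1/SvImJ were 2156 with DESeq2, 163 with DESeq2 size factors, 6 at an adjusted p of 0.01, 187 on autosomes only, 45044 with the first component, 878 with the index, 166 with library size only, 111 with quantile normalization, 157 with limma-trend, 126 with a mean count of at least 20, 8 with the 2 groups alone, 3341 with the replicate block, 73 with thinned libraries, 4493 with voom and the mouse number, 10794 without the 4 libraries and 6 to 25946 when each library was left out. The interaction had 7 calls with DESeq2, 29334 with the first component and 0 to 1 when each library was left out. The F1 calls were 1012 with the deepest SNP, where the filter was applied anew to the lower counts, and 3798 with no low-count filter. In the strain effect on chow against strain effect on HFD the shared calls of equal sign were 7024 at an adjusted p of 0.01 and 20430 with the index, and shared diet calls with the index were 92. A stricter threshold or a 2-fold minimum lowers a count by construction. The first component, taken from deviations within groups, cannot remove a shift between groups. It takes up spread within groups, so the higher counts with it are partly set by construction. For the other settings the cause was not tested.

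The number of gene lists called with the index was 6 for strain on chow, 6 for diet in C57BL/6J, 9 for diet in 129S1/SvImJ and 4 for the interaction, and with an estimated correlation 0 in all 5 comparisons. The lists called in opposite directions without and with the index had adjusted p values with it of 0.0223 (bile acid), 2.07e-07 (fatty acid oxidation), 1.97e-05 (xenobiotic) and 0.0314 (cholangiocyte) for diet in 129S1/SvImJ, and 1.30e-04 (fatty acid oxidation) and 0.00498 (cholangiocyte) for the interaction. Other lists changed sign without a call in 1 of the models, among them lipid droplet for diet in 129S1/SvImJ, which passed with the index alone (0.00696) and not at an estimated correlation (adjusted p = 0.408). Within 5 kb of a gene end the odds ratios that lost their call were 0.990 inside genes for strain on HFD and, for diet in 129S1/SvImJ, 0.989 near a gene end and 1.16 inside genes. No named peak reversed under any alternative. In the diet comparison of 129S1/SvImJ 26 of 30 named peaks lost their call at an adjusted p of 0.01, 23 of 28 with the 2 groups alone and 17 of 28 with thinned libraries.

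Libraries of equal replicate number in different groups differ in strain or diet, and the numbers were not taken to pair them. The correlation of their deviations over 33 pairs ran from -0.61 to 0.82 and exceeded 0.1 in 21, among them all 6 pairs of replicate 1 and all 6 of replicate 5, so a shared factor is not excluded. Within groups 25 pairs of libraries shared a number in the mouse names and 36 did not, with median correlations of deviations of -0.24 and -0.16. The correlation fitted for the random term of this number was -0.08. Whether mice that share a number are independent is not known here. Motif alternatives were not run, and a model of 2 groups alone is not defined for the interaction. On simulated counts with few changed peaks, 25.4% of 2-fold strain differences on chow and 11.9% of 2-fold interactions were recovered. This does not measure recovery where many peaks differ, as between the strains.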

Other observations

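The model with the hepatocyte index, from which the diet values in this part come, and the imprinted genes were chosen only after the results had been seen.

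With the index in the model single peaks near sterol and lipid genes were called for HFD in both strains. As lists, cholesterol synthesis and lipogenesis did not pass in C57BL/6J (camera adjusted p = 0.169 and 0.484), nor did lipogenesis in 129S1/SvImJ (camera adjusted p = 0.152), where the cholesterol list passed at a preset correlation (7.09e-06) and not at an estimated one (adjusted p = 0.188). Abcg5, which encodes a subunit of the sterol exporter of hepatocytes, rose at chr17:84658904-84659131 in C57BL/6J (2.46 ± 0.31, adjusted p = 5.11e-05) and in 129S1/SvImJ (from 1.21 ± 0.483 to 3.22 ± 1.80 CPM, adjusted p = 2.23e-04). Cd36, a fatty acid transporter, rose at chr5:17881459-17881785 (0.85 ± 0.17, adjusted p = 0.0168, and 1.46 ± 0.21, adjusted p = 7.63e-05), and so did Por, the reductase partner of the P450 enzymes, at chr5:135681247-135681397 (0.99 ± 0.20, adjusted p = 0.0181, and 1.83 ± 0.22, adjusted p = 4.47e-06). Sqle fell in both (-1.49 ± 0.21, adjusted p = 3.72e-04, and -2.69 ± 0.24, adjusted p = 1.05e-08), and so did Gys2 (-1.21 ± 0.19, adjusted p = 0.00150, and -1.04 ± 0.21, adjusted p = 0.00734). Scd1, a fatty acid desaturase gene, rose at a different peak in each strain (1.06 ± 0.17, adjusted p = 0.00150, and 1.79 ± 0.21, adjusted p = 1.76e-06). At these peaks 11 to 13 of 13 libraries in C57BL/6J and 8 to 11 of 11 in 129S1/SvImJ lay on the side of their own group in CPM. In total 512 peaks passed in C57BL/6J and 878 in 129S1/SvImJ, and 92 passed in both, 75 higher, 17 lower and 0 in opposite directions, where independent lists would share 1.74 and 0.246. The interaction called 0 peaks with the index in the model.

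By list in the same model, lipid droplet genes had 6 peaks higher and 0 lower in C57BL/6J, with 11 and 0 adjusted over the list alone (camera adjusted p = 1.13e-05, adjusted p = 0.329 with an estimated correlation), including Cidea at chr18:67350811-67350961 (1.87 ± 0.29, adjusted p = 0.00150) and Plin4, a lipid droplet coat gene (0.89 ± 0.19, adjusted p = 0.0232). Fatty acid oxidation genes had 10 higher and 0 lower in 129S1/SvImJ, with 16 and 0 adjusted over the list alone (camera adjusted p = 2.07e-07, adjusted p = 0.188 with an estimated correlation). Without the index the same list was lower, with a median of -0.27 and 0 peaks called higher (camera adjusted p = 5.38e-05), so its direction rests on the index. Among its peaks were the acyl-CoA dehydrogenase gene Acadm (0.99 ± 0.24, adjusted p = 0.0387), with 7 of 11 libraries on the side of their group in CPM, which was 2.73 ± 1.16 on chow and 3.26 ± 1.58 on HFD, and Ppara at chr15:85768942-85769189 (0.79 ± 0.20, adjusted p = 0.0484), with 4 of 11. Gluconeogenesis genes had 2 higher and 8 lower in C57BL/6J, with 5 and 22 adjusted over the list alone (camera adjusted p = 3.02e-05), and 1 higher and 22 lower in 129S1/SvImJ, with 5 and 47 (camera adjusted p = 9.40e-06). With an estimated correlation the adjusted p was 0.329 and 0.188.

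Imprinted genes with a maternally methylated region were read in the F1 table. Of 30 such genes, 7 had peaks there, with 19 peaks of at least 20 allele counts. Counts lay on the 129S1/SvImJ allele for 95% or more at 7 of these peaks, at Impact, Peg10, H13 and Snrpn, and on the C57BL/6J allele at 1, at Cdh15. Over all 20772 autosomal peaks with as many counts the numbers were 296 and 301.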
